A study of Homo sapiens with 15 samples.

How the data were processed

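Chromatin accessibility was measured by ATAC-seq in 15 libraries of human CD4 T cells, of which 13 are labelled CXCR5+ and the 2 ICOS libraries carry no CXCR5 label. In this assay the Tn5 transposase cuts and tags open chromatin, and reads pile up where DNA is accessible. Per the labels' protocols, frozen cells were thawed, rested overnight and sorted before transposition and paired-end sequencing. The libraries fall into 7 groups by tissue and surface marker. The lymph node (LN) gave 2 PD-1- and 3 PD-1+ libraries, the thoracic duct (TD) gave 2 PD-1 dim and 3 PD-1 bright libraries, and blood mononuclear cells (PBMC) gave 3 PD-1+ libraries, 1 ICOS low library and 1 ICOS Hi library. The TD tissue label names both the thoracic duct and a lymph node, and it is called TD here without deciding between them. The labels name no donors, so replicates were not paired, and p-values measure only the spread between these libraries, which may be technical or between people.

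The deposited files hold raw read counts, 1 count per called peak, with no header. Each library has its own peak list, so a region missing from a list has no value rather than a count of 0. Bowtie2, MACS 1.4, bedtools and HOMER are named with the hg19 build in the submitters' processing notes. Their roles and settings, including any shift of reads for the Tn5 cut site and the treatment of duplicate reads, are not given in the sources used here. Starts were read as BED positions and are printed counted from 1. The files do not state this convention, so a start can be off by 1 bp. No annotation of the hg19 build was used here, so regions are given by position only, without gene names. The gene lists of the plan were therefore not tested.

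Peaks on the 22 autosomes were merged into 187923 union regions wherever peaks of any libraries overlapped by at least 1 bp, and counts of several peaks of a library in a region were summed. Peaks off the autosomes held 3.65% of all counts and were left out of the values printed. No filter for repeats or poorly mapped positions was applied here, so such positions may be among the regions named. Counts scaled to a total of 1000000 (CPM) used each library's total autosomal count in peaks. For tested regions and the ICOS pair these totals were multiplied by TMM normalization factors, so the CPM of a region can differ slightly between comparisons. For called-only regions the plain totals were used. The plain totals ran from 839105 to 3974251, and the smallest peak in any list held 3 counts. No pair of libraries had more than 116 peaks with identical bounds, so all libraries were counted separately. Accessibility was compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter and Benjamini-Hochberg adjustment at 0.05. Each fit held the libraries of the groups compared and the regions called in all of them. Standard errors were derived from the fold change and the F statistic. Regions called in every library of one group and in none of the other were counted without a test. The difference between the PD-1 effects in LN and TD was tested as an interaction over 10 libraries.

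The regions higher in LN PD-1+ than LN PD-1- were tested as a set in TD, with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry (limma 3.58.1, voom weights). By a rule set beforehand, a set of fewer than 50 regions was replaced by the 500 regions of that direction with the lowest p. This applied to the lower set, and to the higher set without LN PD-1+ replicate 2, without LN PD-1- replicate 2 and with the width offset. For ICOS Hi and ICOS low, with 1 library each, the set's median log2 ratio (prior count 2) was placed among 10000 random region sets matched on mean count. Single values per library were compared with 2-sided exact permutation tests, whose smallest possible p is 0.1 for 3 against 3 libraries and 0.2 for 3 against 2. Intervals on shares are 95% Wilson intervals. Intervals on ICOS ratios are exact binomial ones, and both cover counting error only.

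Regions named in the text were chosen by a rule fixed before the data were examined. It took the 5 regions per direction with the largest fitted change among those past the threshold whose groups did not overlap. Where no region passed, it took the 10 regions per direction with the highest mean CPM among those called in one group only, and for ICOS the 10 largest ratios each way at a mean CPM over 10. Regions named outside this rule are marked as such. Alternatives were DESeq2 1.42.0, other normalizations, filters, merging rules and list lengths, and leaving out each library. The mean level of the set per library, the log2 ratio of shares, the width offset and the loess correction were added after the data had been seen.

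The tests were tested on simulated data with 100 regions changed at each fold (99 for the 2-fold changes between LN and blood). For LN PD-1+ against LN PD-1-, over 18463 simulated regions, 27% of 2-fold and 85% of 4-fold changes were recovered. For TD bright against dim, over 13674 regions, the shares were 17% and 75%. For LN PD-1+ against PBMC PD-1+, over 15003 regions, they were 39.4% and 96%. For TD bright against PBMC PD-1+, over 13889 regions, they were 30% and 90%, and for TD bright against LN PD-1+, over 14823 regions, they were 40% and 97%. False calls numbered between 3 and 11 per comparison. Of 100 unshifted simulated sets, 7 lay outside the 95% range of matched random sets, and 73 of 100 shifted sets lay above it. All simulated values were drawn independently for each region, with no correlation between regions and no differences in called width. The real libraries have both, and regrouping them across sorts gave up to 193 calls. The simulated rates therefore hold for that setting only and may be too favourable.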

Results

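The data describe open chromatin in sorted CD4 T cells from LN, TD and blood. Of the libraries, 13 are labelled CXCR5+, the population that holds T follicular helper (Tfh) cells, and 2 blood libraries are labelled only by ICOS. CXCR5 is the chemokine receptor that guides T cells to B cell follicles, PD-1 is an inhibitory receptor carried at high level by germinal centre Tfh cells, and ICOS is a costimulatory receptor of activated Tfh cells. The 15 libraries held between 29362 and 74269 called autosomal regions. LN PD-1+ libraries had the most regions among the replicated groups, at 44501 ± 4392 (SD, n = 3). LN PD-1- libraries had 35638 ± 3504 (SD, n = 2), PBMC PD-1+ libraries 34189 ± 4982 (SD, n = 3), TD PD-1 bright libraries 34260 ± 6371 (SD, n = 3) and TD PD-1 dim libraries 33516 ± 318 (SD, n = 2). LN PD-1+ exceeded PBMC PD-1+ with an exact permutation p of 0.1, the smallest this design can give. Counts in peaks averaged 2117695 ± 934008 in LN PD-1+ and 1351702 ± 237344 in PBMC PD-1+ (SD, n = 3 each, exact permutation p = 0.3). The mean depth was thus not equal between them. Depth here means counts in called peaks, which also depend on the peaks called, and total reads per library were not known. The mean number of regions with at least 10 counts in TD PD-1 dim was 19815.5.

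**Figure D1:**
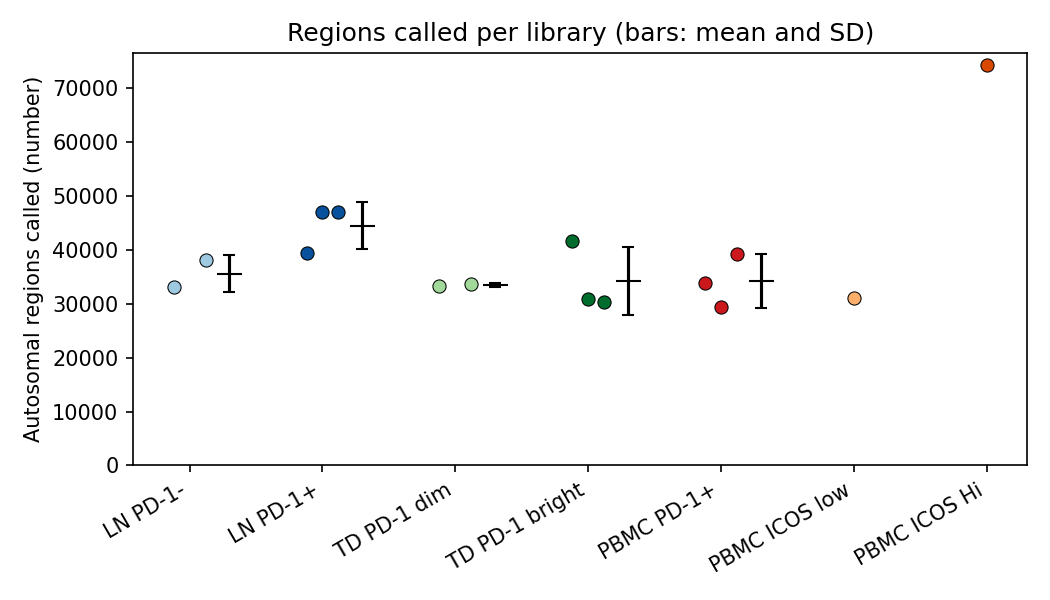
Number of autosomal regions called (vertical axis) in each library (points) by group, with the mean and SD beside groups of more than 1 library. The single ICOS Hi library, at 74269 regions, lies above all other libraries, and LN PD-1+ averaged 44501.

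Most regions belonged to a single library. Of the 187923 union regions, 125066 (66.55%) were called in 1 library, with a median width of 90 bp. A core of 10094 regions (5.37%) was called in all 15 libraries, with a median width of 585 bp, and it held between 56.6% and 75.4% of each library's counts. Over this core the first principal component, 29.1% of the variance, set the 5 LN libraries apart, between 14.94 and 39.36. TD PD-1 bright replicate 1 lay with them at 13.89, while the other 4 TD libraries and all 5 PBMC libraries lay between -31.65 and -3.36. The 3 LN PD-1+ libraries resembled each other most, with a mean correlation of log2 CPM across regions of 0.914, against 0.843 among the TD PD-1 bright libraries. Regions are not independent replicates. TD PD-1 bright replicate 2 correlated more closely with TD PD-1 dim replicate 2 (0.911) than with TD PD-1 bright replicates 1 and 3 (0.825 and 0.846). The highest correlation among the 3 bright libraries was 0.858, between replicates 1 and 3.

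**Figure D2:**
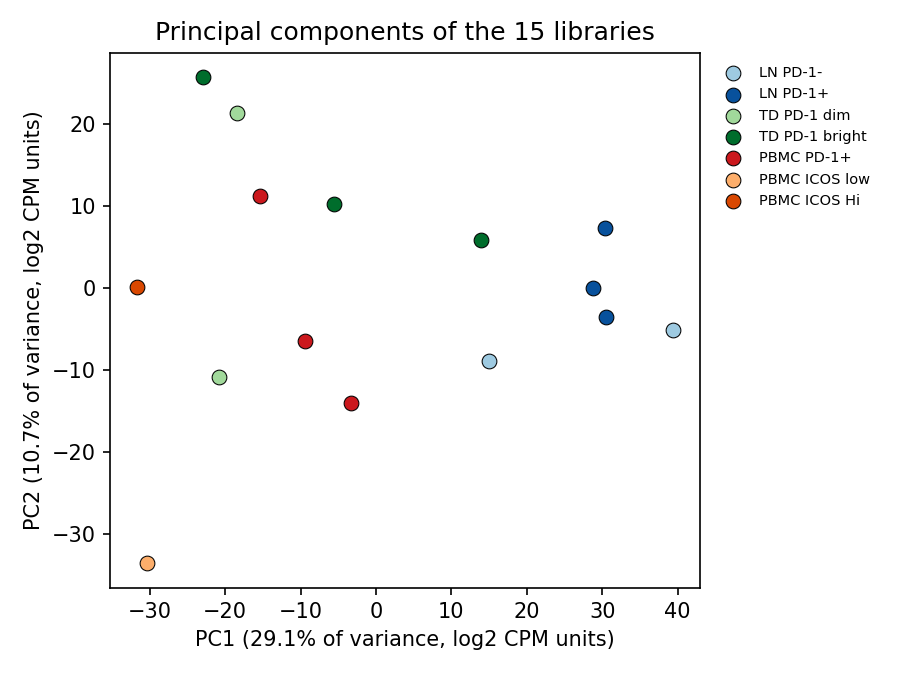
First and second principal components (axes, log2 CPM units) of the 15 libraries (points, coloured by group) over the 10094 regions called in all of them. The LN libraries lie at 14.94 or higher on the first axis, with TD PD-1 bright replicate 1 next to them at 13.89.

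Within the lymph node, PD-1+ cells had 135 regions of higher and 36 of lower accessibility than PD-1- cells. The largest gain was at chr10:310257-311323 (hg19), with 105 ± 52.3 CPM in PD-1+ and 8.61 ± 7.42 CPM in PD-1- libraries (SD, n = 3 and 2), a log2 fold change of 3.61 ± 0.64 (SE, adjusted p = 0.0437). At chr4:146220697-146221177 accessibility was 76 ± 15.1 CPM against 10 ± 5.44 CPM, a log2 fold change of 2.92 ± 0.35 (adjusted p = 0.00104). The regions chr11:93254318-93254700, chr5:158768887-158769239 and chr10:63520673-63521246 were 7.9-fold, 7-fold and 6.67-fold higher. The largest loss was at chr2:161933931-161934731, with 3.04 ± 1.14 CPM in PD-1+ and 22.9 ± 9.37 CPM in PD-1- libraries, a log2 fold change of -2.95 ± 0.50 (adjusted p = 0.00984). The regions chr10:67260948-67261295, chr1:193448360-193448825, chr6:130453377-130453801 and chr2:113754274-113754547 were between 4.94-fold and 6.13-fold lower in PD-1+ cells. A further 1731 regions were called in all PD-1+ and no PD-1- libraries, and 600 the other way. With the same number of top peaks these were 1059 and 834, and the direction turned without LN PD-1- replicate 1 (3423 and 8740) or replicate 2 (3308 and 4941), where a single library was left to define the PD-1- side.

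Among the 10 named regions, only chr4:146220697-146221177 stayed past the edgeR threshold with each library left out and with the width offset (log2 fold change 1.72). At chr10:310257-311323 the log2 fold change was 4.92 without LN PD-1- replicate 1, 2.91 without LN PD-1- replicate 2 and 3.39 without LN PD-1+ replicate 2 (edgeR adjusted p = 0.058, 0.207 and 0.0615), and 1.67 with the offset. At chr2:161933931-161934731 it was -2.47 without LN PD-1- replicate 1 and -2.61 without LN PD-1+ replicate 2 (edgeR adjusted p = 0.0732 and 0.0658), and -0.86 with the offset (edgeR adjusted p = 0.814). Of the 10 regions, 8 missed the threshold without LN PD-1- replicate 2, 7 without LN PD-1- replicate 1, 6 without LN PD-1+ replicate 2, 2 without LN PD-1+ replicate 1, 2 without LN PD-1+ replicate 3 and 6 with the offset, while all kept their direction.

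The edgeR test covered 18517 regions, of which 2356 had an unadjusted p under 0.05 where 926 would be expected by chance. Other splits of the same 5 libraries gave 336 to 1546 such regions, and 0 calls each. Splits that kept both PD-1- libraries together gave 1546, 1292 and 455, the last with LN PD-1+ replicate 2 beside them. They share part of the real grouping, so they cannot show how far 926 holds as the chance level. The number of calls was 19 without LN PD-1- replicate 2, 40 without LN PD-1+ replicate 2, 86 without LN PD-1- replicate 1 and 111 without LN PD-1+ replicate 1, and it was 28 with an offset for the called width of each peak (16 higher and 12 lower), 268 with DESeq2, and 0 with uncalled regions at 0 on regions called in every library of either group, and also 0 with the count filter dropped and regions called in at least 50% of each group, which changed 2 choices at once.

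In TD the same marker gave no region past the threshold in the edgeR test. Of 13707 regions tested, 480 had an unadjusted p under 0.05 against 685 expected by chance, and DESeq2 also called 0. Regions called in all PD-1 bright and no PD-1 dim libraries numbered 766, and 396 were called the other way. The direction turned without TD PD-1 dim replicate 1 (1378 and 9643) or replicate 2 (2559 and 12211), where a single library was left to define the dim side. The bright-only regions of highest accessibility were chr9:5110150-5110262 at 54.4 ± 16.3 CPM, chr7:92260723-92261266 at 34.3 ± 17.3 CPM and chr4:185203448-185203855 at 32.3 ± 19.7 CPM (SD, n = 3 each), and the other 7 named by the same rule lay between 26 and 31.1 CPM. The dim-only regions of highest accessibility were chr2:133028360-133028509 at 36.2 ± 23 CPM and chr20:62270668-62270824 at 27.7 ± 4.64 CPM (SD, n = 2 each), and the other 8 lay between 24 and 26.2 CPM. The called-only regions carry no test. The simulated recovery of 17% of 2-fold changes limits what a count of 0 can exclude here.

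Of the 135 regions that were higher in LN PD-1+ cells, 52 could be tested in TD. Of these, 51 (98.1%) had a positive log2 fold change for TD PD-1 bright against dim, against 48.4% of all regions, with a median of 0.66, but the set was not past the threshold in camera with an estimated correlation between regions (p = 0.0682) or in fry (p = 0.124). With TD values corrected for called width, 40 of the same 52 regions were positive with a median of 0.328. With the LN test corrected as well, which made a set of 500 regions, 148 of 264 were positive with a median of 0.071. The median over all TD regions was -0.123 with the width correction and -0.013 without it. Over the 27 set regions called in all 15 libraries, the mean log2 CPM relative to the 15-library mean was 0.31, -0.30 and 0.29 in the TD PD-1 bright libraries and -0.46 and -0.75 in the TD PD-1 dim libraries. It was 0.92 or higher in the LN PD-1+ libraries and between -0.34 and -0.10 in the PBMC PD-1+ libraries. The lower set showed no such shift, with a median of -0.01 over 399 regions.

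Camera with the preset correlation gave p = 4.8e-19 for the higher set, but p = 0.0682 with an estimated correlation, and p = 0.183 with the width-corrected TD values and an estimated correlation. For the lower set camera gave p = 0.521, and p = 0.729 with an estimated correlation. The difference between bright and dim libraries in mean level had an exact permutation p of 0.2, the smallest possible with 3 against 2 libraries. The median was 0.35 without TD PD-1 bright replicate 1 and 0.30 with the 1000 higher regions of lowest p. Where fewer than 50 regions were called, the 500 of lowest p formed another set. There the median was 0.39 without LN PD-1+ replicate 2, 0.17 without LN PD-1- replicate 2 and 0.35 with the width offset in the LN fit. Without TD PD-1 dim replicate 1 or 2, which left a single dim library, the median was 0.68 each time. The estimated-correlation camera p was 0.117, 0.0172 and 0.141 without TD PD-1 bright replicates 1, 2 and 3. It was between 0.0775 and 0.102 with an LN PD-1+ library left out. Without LN PD-1- replicate 2 it was 0.0357, with a single PD-1- library left to define the set.

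**Figure D3:**
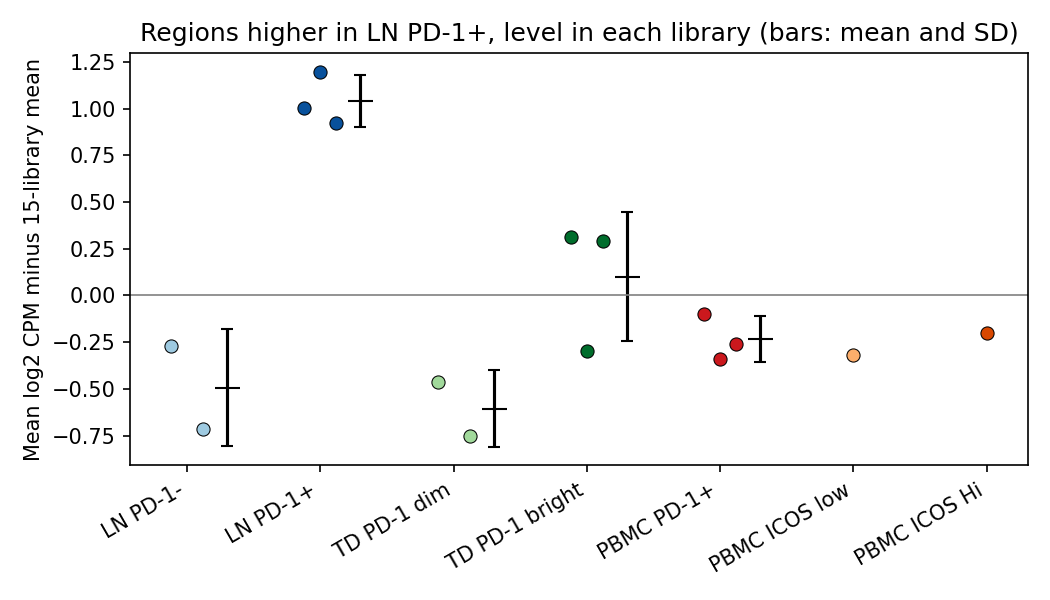
Mean log2 CPM relative to the 15-library mean (vertical axis) of the 27 regions higher in LN PD-1+ and called in every library, in each library (points) by group, with the mean and SD beside groups of more than 1 library. The LN PD-1+ points lie at 0.92 or higher by the choice of regions, and TD PD-1 bright replicate 2, at -0.30, lies near the dim and blood libraries.

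Of the 1731 regions called only in LN PD-1+ within the node, TD PD-1 bright libraries called 42.6% (95% interval 40.3 to 44.9), 28.4% (26.3 to 30.5) and 19.9% (18.1 to 21.9). TD PD-1 dim libraries called 14.7% (13.1 to 16.5) and 23.5% (21.6 to 25.6), and PBMC PD-1+ libraries between 18.9% and 29.8%. Union regions called in the same number of other libraries were called at 41.4%, 29.6% and 21.9% in the TD PD-1 bright libraries and at 22.2% and 27% in the TD PD-1 dim libraries, so the bright shares were 1.03, 0.96 and 0.91 of that level and the dim shares 0.67 and 0.87. Relative to the 600 regions called only in LN PD-1-, the log2 ratio of shares was 0.17 ± 0.17 (SD, n = 3) in TD PD-1 bright, -0.39 ± 0.44 (SD, n = 2) in TD PD-1 dim and -0.26 ± 0.33 (SD, n = 3) in PBMC PD-1+. The exact permutation p was 0.2 for bright against dim, the smallest possible, and 0.2 for bright against blood. With the same number of top peaks per library the log2 ratios were -0.18 ± 0.18, -0.87 ± 0.30 and -0.77 ± 0.29 in the same order, so the bright value turned negative, and the exact permutation p was 0.2 against dim and 0.1 against blood, each the smallest possible.

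The PD-1 effects in LN and TD were also compared directly. The edgeR interaction test over 12445 regions called none, with 621 at an unadjusted p under 0.05 where 622 would be expected, and DESeq2 called 0. A difference between the effects was not detected at this depth and number of libraries.

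Between node and blood, PD-1+ cells differed at 1267 regions, 746 higher and 521 lower in the node. The largest gain was at chr1:214612680-214613380, with 118 ± 11.9 CPM in LN and 10.1 ± 5.8 CPM in PBMC libraries (SD, n = 3 each), a log2 fold change of 3.61 ± 0.29 (adjusted p = 1.19e-06). The region chr8:101475955-101476709 had 117 ± 0.44 CPM against 12.9 ± 5.04 CPM, a log2 fold change of 3.19 ± 0.25 (adjusted p = 1.19e-06), and chr12:67843334-67843770, chr5:123919333-123919930 and chr8:103548022-103548679 were between 8.93-fold and 9.82-fold higher. The largest loss was again at chr2:161933931-161934731, with 3.15 ± 1.17 CPM in LN and 43.4 ± 24.2 CPM in PBMC, a log2 fold change of -3.83 ± 0.48 (adjusted p = 0.000105). This comparison shares its LN PD-1+ libraries with the one inside the node. The regions chr17:2717759-2718643, chr18:21451262-21451635, chr4:8411077-8411707 and chr2:192604685-192605165 were between 6.25-fold and 7.97-fold lower in the node. Regions called in all libraries of one group and none of the other numbered 2469 for LN PD-1+ and 217 for PBMC PD-1+. With the same number of top peaks these were 1486 and 583, and with a library left out, so that fewer libraries had to meet the rule, 3120 to 5011 and 288 to 626.

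The edgeR test covered 15035 regions, with 3553 at an unadjusted p under 0.05 against 752 expected. Scaling by library totals alone gave 637 higher and 814 lower regions, and the count of calls was 184 with the width offset (89 higher and 95 lower), 260 with the count filter dropped and regions called in at least 50% of each group, 2067 with uncalled regions at 0, and 611 without LN PD-1+ replicate 2. All 10 named regions stayed past the threshold with each library left out, and with the width offset the log2 fold change was 2.17 at chr1:214612680-214613380, 1.36 at chr8:101475955-101476709 and, no longer past the threshold, 0.81 at chr8:103548022-103548679 and -1.43 at chr2:161933931-161934731 (edgeR adjusted p = 0.255 and 0.0837).

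TD PD-1 bright and PBMC PD-1+ cells differed at no region in the edgeR test. Of 13912 regions tested, 706 had an unadjusted p under 0.05 against 696 expected by chance. DESeq2 called 2 regions, named here after their values were seen. These were chr4:78507993-78508587, with a log2 fold change of 1.59 ± 0.31 toward TD, and chr19:6767421-6768276, with -1.89 ± 0.36 (DESeq2 adjusted p = 0.00164 for each), whereas their edgeR adjusted p were 0.0986 and 0.15. Regions called in all libraries of one group and none of the other numbered 295 for TD PD-1 bright and 253 for PBMC PD-1+, a direction that turned with the same number of top peaks (250 and 299) and without PBMC PD-1+ replicate 1 (482 and 754), PBMC PD-1+ replicate 2 (528 and 747) or TD PD-1 bright replicate 1 (631 and 759). The most accessible TD-only region was chr2:83043518-83043624 at 229 ± 55 CPM, and the other 9 lay between 20.5 and 42 CPM. The most accessible blood-only regions were chr5:5395769-5395956 at 126.8 ± 58.3 CPM and chr9:94873052-94873145 at 63.7 ± 10.9 CPM (SD, n = 3 each). These 3 regions were narrow, at 107, 188 and 94 bp. The number of calls was 2 with uncalled regions at 0, which called the TD-only region on chromosome 2 and the blood-only region on chromosome 9, 2 with the width offset, 2 without TD PD-1 bright replicate 2 and 1 without TD PD-1 bright replicate 3.

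TD PD-1 bright cells differed from LN PD-1+ cells at 230 regions, 65 higher and 165 lower in TD. The largest loss in TD was at chr6:135858835-135859466, with 6.35 ± 4.17 CPM against 54.4 ± 13.7 CPM in LN (SD, n = 3 each), a log2 fold change of -3.22 ± 0.44 (adjusted p = 0.00296). The regions chr10:363171-363562, chr12:92566345-92566797, chr7:50237266-50237666 and chr13:74445102-74445438 were between 5.55-fold and 7.17-fold lower in TD. The largest gain was at chr17:2717759-2718643, with 53 ± 19 CPM against 8.42 ± 3.35 CPM, a log2 fold change of 2.70 ± 0.41 (adjusted p = 0.0048). This region was also lower in LN PD-1+ than in PBMC PD-1+, a comparison that uses the same LN libraries. The regions chr15:92400960-92401516, chr2:183517108-183517426, chr2:222382967-222383553 and chr4:153021495-153022198 were between 4.27-fold and 5.25-fold higher in TD. Regions called only in TD PD-1 bright numbered 131, and 1679 were called only in LN PD-1+. With the same number of top peaks these were 374 and 1039, and with a library left out 183 to 612 and 2042 to 3902.

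The edgeR test covered 14860 regions, with 2507 at an unadjusted p under 0.05 against 743 expected, and library totals alone gave 97 higher and 108 lower. Every left-out library moved the count, to 42, 15 and 62 without LN PD-1+ replicates 1, 2 and 3 and to 807, 121 and 38 without TD PD-1 bright replicates 1, 2 and 3, and it was 458 with DESeq2, 47 with the width offset (22 higher and 25 lower), 0 with uncalled regions at 0, and 0 with the count filter dropped and regions called in at least 50% of each group. Of the 10 named regions, 7 missed the threshold with the width offset, with a log2 fold change of -0.98 at chr6:135858835-135859466 and 1.21 at chr17:2717759-2718643 (edgeR adjusted p = 0.37 and 0.11), and 4, 2 and 2 missed it without LN PD-1+ replicate 2, LN PD-1+ replicate 1 and TD PD-1 bright replicate 3.

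**Figure D4:**
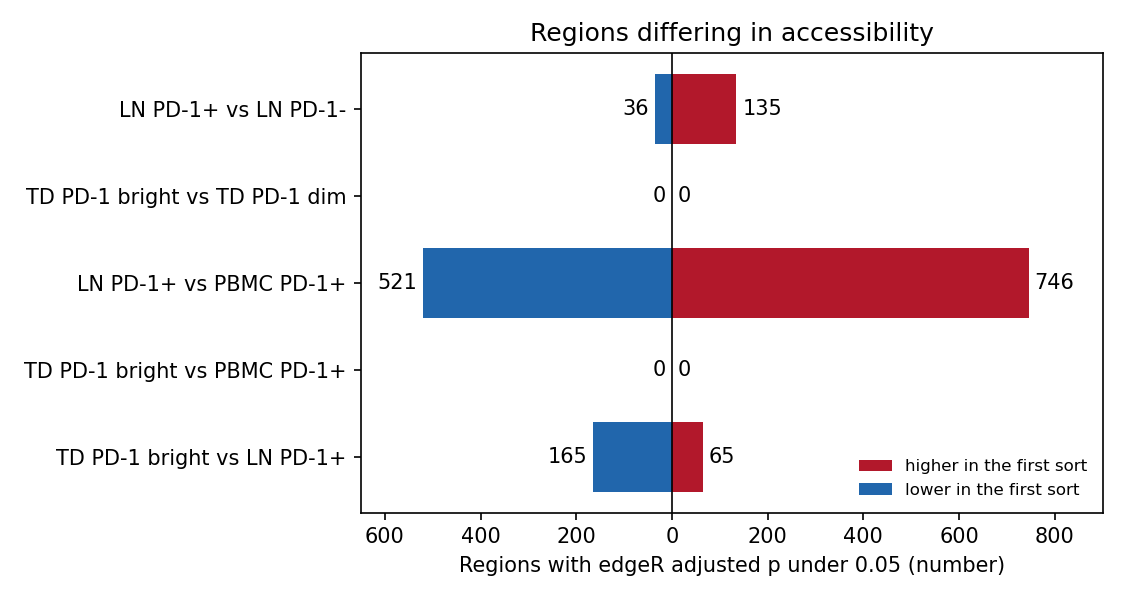
Number of regions past an edgeR adjusted p of 0.05 (horizontal axis) for each comparison (vertical axis), higher (right, red) or lower (left, blue) in the sort named first. LN PD-1+ against PBMC PD-1+ had 746 higher and 521 lower regions, and both TD PD-1 bright comparisons without LN PD-1+ had 0.

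In blood, ICOS Hi and ICOS low cells had 1 library each, so the values compare those libraries and carry no replicate check. Among 16666 regions called in both with a mean CPM over 10, 1423 had a log2 ratio over 1 toward ICOS Hi and 3687 a log2 ratio under -1. These were 1136 and 1751 at a mean CPM over 20, and 1425 and 4643 at a mean CPM over 5. The smallest peak held 5 of 962141 counts in ICOS low and 4 of 3974251 in ICOS Hi. The need for a call in both thus limited ratios toward ICOS Hi more, so the excess toward ICOS low cannot be read as a difference between the cells. Over all regions the imbalance was the other way, with 55767 called only in ICOS Hi and 12637 only in ICOS low, and with the same number of top peaks it was 14035 and 13968. Ranked by the log2 ratio with a prior count of 2, the first region toward ICOS Hi was chr20:2082386-2083758, 68.6 against 7.1 CPM, a 9.67-fold difference (95% interval 4.63 to 24.3), followed by chr6:42713737-42714369 at 8.04-fold (4.32 to 16.9) and chr3:71136328-71137140 at 7.89-fold (4.1 to 17.4). The first toward ICOS low was chr2:133028939-133029324, 593 against 27.9 CPM, a 21.3-fold difference (17.3 to 26.4). The ICOS Hi library had 4.13 times the counts of the ICOS low library, and its median peak width was 117 bp against 99 bp.

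The LN PD-1+ higher set had a median log2 ratio of 0.21 toward ICOS Hi over 48 regions, at the 84.05 percentile of matched random sets. The 1000 regions of lowest p, of which 404 were called in both libraries, had a median of 0.46 at the 100 percentile, while matching the main set on width as well placed it at the 44.9 percentile. The lower set had a median of 0.02, at the 0 percentile with and without matching on width. The set of 1000 regions was not matched on width. Random sets treat regions as independent, and ICOS Hi and ICOS low had a single library each. The percentiles therefore cannot show whether the cells differ at these regions. Of the 1731 regions called only in LN PD-1+ within the node, ICOS Hi called 59.6% (95% interval 57.3 to 61.9) and ICOS low 5.2% (4.25 to 6.35), against 72.2% and 12.3% for regions called in as many other libraries. The ICOS Hi list was longer. With the same number of top peaks, over 1059 such regions, the shares were 29.1% and 5.57%, against 41.7% and 14.5%.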

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

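The LN PD-1+ region chr6:130453377-130453801 pointed in opposite directions in LN and TD, which was the rule that marked it. Its log2 fold change was -2.36 ± 0.44 (SE) between LN PD-1+ and LN PD-1- (edgeR adjusted p = 0.0198), whereas between TD PD-1 bright and dim it was 0.633 ± 0.508 (SE), with every bright library above every dim library in CPM. Of all TD regions tested, 18.69% had bright and dim libraries that did not overlap, in either direction, so this separation is not unusual. The rule could compare 3 named LN regions in TD. The TD value of this region did not pass the edgeR test (adjusted p = 1). In the edgeR interaction test the difference was -2.93 ± 0.62 (SE) with an adjusted p of 0.942, so a difference between the effects was not established. The LN value missed the threshold without LN PD-1- replicate 1, LN PD-1- replicate 2 or LN PD-1+ replicate 2 (edgeR adjusted p = 0.0506, 0.142 and 0.117) and with the width offset (log2 fold change -1.24, edgeR adjusted p = 0.269).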

How the results depend on the processing

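The TD bright against dim comparison and the interaction stayed at 0 regions under every setting run, and the positive median of the LN PD-1+ higher set in TD kept its sign in every setting. It was lowest, at 0.071, with a set of 500 regions and width corrected in both LN and TD (median over all TD regions -0.123). It lay between 0.348 and 0.869 with a TD library left out and the set unchanged, and at 0.388 and 0.171 without LN PD-1+ replicate 2 and LN PD-1- replicate 2, where a set of 500 regions took the place of the called one. The width offset, chromosome X, the 9-library regions and the loess correction were chosen after seeing the data. Fits of only the groups compared were already the reported ones, and the gene lists were not run. No paired analysis was possible because the labels name no donors and the replicate numbers only name libraries. The cause of each change below was not tested, except that leaving out a library lowers the number of libraries a called-only region must meet.

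For LN PD-1+ against LN PD-1- (171 regions), the count was 268 with DESeq2, 28 with the width offset (16 higher and 12 lower), 0 with uncalled regions at 0, and 0 with the count filter dropped and regions called in at least 50% of each group, and ran from 19 to 154 with a library left out. For LN PD-1+ against PBMC PD-1+ (1267) it was 2067 with uncalled regions at 0, 260 with that same pair of changes, 184 with the offset, and 611 to 1280 with a library left out. For TD bright against LN PD-1+ (230) it was 458, 47, 0 and 0 with DESeq2, the offset, uncalled regions at 0 and that pair of changes, 124 on regions called in all 9 libraries, and 15 to 807 with a library left out. For TD bright against PBMC PD-1+ (0) it was 2 with DESeq2, 2 with the offset, 2 with uncalled regions at 0, and 0 to 2 with a library left out.

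With the same number of top peaks per library, the regions called only in LN PD-1+ numbered 1059 against LN PD-1- (834 the other way) and 1486 against PBMC PD-1+, those only in PBMC PD-1+ 583, and TD bright against LN PD-1+ gave 374 and 1039. With a library left out the ranges were 2328 to 4094 for LN PD-1+ only and 789 to 8740 for LN PD-1- only, 3120 to 5011 and 288 to 626 for LN PD-1+ and PBMC PD-1+, 183 to 612 and 2042 to 3902 for TD bright and LN PD-1+, 482 to 1383 and 391 to 759 for TD bright and PBMC PD-1+, and 1253 to 2559 and 538 to 12211 for TD bright and dim. The mean number of regions with at least 10 counts was 28071.5 in LN PD-1-, 32037 in LN PD-1+, 22742 in PBMC PD-1+, 19815.5 in TD dim and 23270.3 in TD bright. The median of the LN lower set in TD (-0.011) ran from -0.072 to 0.07. In the ICOS pair, 1751 regions fell under a log2 ratio of -1 at a mean CPM over 20, the higher set's median was 0.464 with 1000 regions, and the lower set's median (0.021) was -0.020 with 200 regions and -0.050 with library totals alone.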

Other observations

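Regions called only in LN PD-1+ were clustered in places. Against PBMC PD-1+, 5 of 1643 windows of 1000000 bp held more such regions than the background share of 10.48% (hypergeometric test, Benjamini-Hochberg adjusted). On chromosome 13, from 39000001 to 40000000, 8 of 10 regions were of this kind (adjusted p = 0.000874), and on chromosome 6, from 135000001 to 136000000, it was 14 of 33 (adjusted p = 0.0018). Against LN PD-1-, 1 window passed, on chromosome 16 from 89000001 to 90000000, with 11 of 32 regions (adjusted p = 0.0162). Against TD PD-1 bright, 0 of 1643 windows passed (lowest adjusted p = 0.457), and for regions called in TD PD-1 bright only against dim it was 0 of 1406 (lowest adjusted p = 0.355). Neighbouring regions are not independent, so these p-values are too small by an unknown amount. These windows were examined only after the region counts were seen.

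Of the tests below, those on leaving out a TD bright library, camera on width-corrected TD values, on width between LN and blood, on list length, on splits of the 3 against 3 comparisons and both hypotheses were chosen after related results were seen. The loess correction, the width correction in TD and the splits of the TD libraries were chosen before their own results were seen, though after the region tests had been run.

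The higher level of LN PD-1+ regions in TD PD-1 bright than dim may reflect shared chromatin features of PD-1 high cells, a hypothesis that stays open. Called peak width cannot be excluded. Its correction cannot decide the matter, since widths were called in the libraries that gave the counts and it may also remove part of a real change. With the same 52 regions and TD values corrected for width the median log2 fold change was 0.328 in place of 0.657, with 40 in place of 51 positive and camera p = 0.183 with an estimated correlation. With the LN test corrected as well, which made a set of 500 regions, the median was 0.071 with 148 of 264 positive and camera p = 0.345 with an estimated correlation. In both settings the median over all TD regions was -0.123, against -0.013 without the correction. From edgeR fold changes the medians in these settings were 0.372 (42 of 52 positive) and 0.088 (154 of 264 positive), each at the 100 percentile of matched random sets. Those sets treat regions as independent, whereas the estimated correlations were 0.501 and 0.327. A single bright library was not needed for a positive median, which was 0.348, 0.869 and 0.596 without replicates 1, 2 and 3 (46 of 52, 52 of 54 and 53 of 57 positive). From edgeR fold changes the medians were 0.455, 0.855 and 0.631, each at the 100 percentile of such random sets. The share of a single library in the size stays open. Camera p with an estimated correlation reached 0.141 but was 0.0682 already with all 5 libraries and cannot decide it. Of the 10 splits of the 5 TD libraries 2 gave a median as far from 0, the real one with 0.711 (edgeR fold changes) and another with 0.812 in size. The latter had TD PD-1 bright replicate 2 beside both dim libraries. At least 2 such splits was the outcome set beforehand for a grouping by chance, which therefore stays possible. The 10 splits are too few for a share under 0.05.

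The difference between LN PD-1+ and PBMC PD-1+ may be biological or may follow from donors or handling, which the labels do not separate from tissue. Depth also differed, at 2117695 ± 934008 and 1351702 ± 237344 counts (SD, n = 3 each), and was not tested as a cause. LN PD-1+ replicate 2 held 3136923 counts, the most of these 6 libraries. Without it 611 regions passed, against 846 to 1280 with another library left out. A loess correction against mean abundance left 1343 calls, of which 1244 were among the 1267 original ones. This argues against a smooth trend of signal with region abundance as the source of most calls. Unequal transposition that leaves no such trend was not tested. Called width as a cause stays open. The called regions' median log2 fold change in the direction of the call was 0.654 ± 0.364 (SD over regions) after correction and 1.23 ± 0.47 before. Of the 1267 regions, 1245 kept their sign. Regions and directions were chosen on the uncorrected counts of the same libraries, which favours a kept sign, so these values cannot decide it. After the correction only 184 regions passed, 89 higher and 95 lower, because folds shrank while standard errors did not (median 0.295 before and 0.294 after). Of the 10 splits only 1, the real one, gave as many as 1267 regions and the highest other gave 0, and 10 splits are too few for a share under 0.05.

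More regions were called only in LN PD-1+ (2469) than only in PBMC PD-1+ (217), a ratio of 11.4, which was 5.15 without PBMC PD-1+ replicate 1 and 17.4 without LN PD-1+ replicate 1. Longer peak lists in LN PD-1+ may account for much of this, since with the same number of top peaks the ratio was 2.55. They do not account for all of it, as the lowest ratio of such lists on leaving out a library was 1.553, without PBMC PD-1+ replicate 1. Unequal depth within lists of equal length stays open.

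For TD PD-1 bright against LN PD-1+, 1 of 10 splits, the real one, gave as many as 230 regions, and the highest other gave 0. For TD PD-1 bright against PBMC PD-1+ the real split gave 0, so that all 10 splits gave at least as many by construction and their number says nothing about chance. The highest other gave 193, which points to a structure of the samples. It set PBMC PD-1+ replicates 1 and 2 with TD PD-1 bright replicate 3, the 3 libraries with the fewest counts of the 6 (894534 to 1401682, against 1478178 to 1624440). For TD PD-1 bright against dim, where the real split gave 0, the split of TD PD-1 dim replicate 1 and bright replicate 3 against the other 3 libraries gave 99. These 2 had the fewest counts (839105 and 894534, against 1351116 to 1624440) and the narrowest peaks (median 104 and 129 bp, against 148 to 166 bp) of the 5. Both splits followed depth, which was seen only afterwards and was not tested as the cause. In each comparison, 10 splits are too few for a share under 0.05. Regions at an unadjusted edgeR p under 0.05 in a split other than the real one numbered up to 1321 for TD PD-1 bright against dim (685 expected). They numbered up to 1159 for TD PD-1 bright against PBMC PD-1+ (696 expected) and up to 1340 against LN PD-1+ (743 expected). For LN PD-1+ against PBMC PD-1+ the highest was 631 (752 expected).

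A hypothesis was that regions higher in LN PD-1+ than LN PD-1- are also higher in TD PD-1 bright than in PBMC PD-1+. Of 56 regions tested, 43 (76.8%) were positive, with a median log2 fold change of 0.60 and camera p = 4.91e-11 at the preset correlation, but p = 0.11 with an estimated correlation. Another was that regions higher in LN PD-1+ than in blood are higher in TD PD-1 bright than in TD PD-1 dim. Of 529 regions, 406 (76.8%) were positive, with a median of 0.30 and camera p = 8.98e-15, but p = 0.207 with an estimated correlation. Neither hypothesis is settled by these libraries.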
